A study of Mus musculus with 9 samples.

How the data were processed

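The study profiled the transcriptome of Lgr5-GFP+ intestinal stem cells (ISCs), the crypt base cells that renew the epithelium of the mouse small intestine. Per the labels' protocols, the mice carried an Lgr5-EGFP-CreERT2 allele, which drives green fluorescent protein and a tamoxifen-inducible Cre recombinase in these cells, and loxP-flanked Kansl1 alleles. KANSL1 is the scaffold of the NSL complex, a histone acetyltransferase complex built around the enzyme KAT8. Mice received tamoxifen daily for 3 or 4 days (KO day 3 and KO day 4) or corn oil (control), and GFP+ cells were sorted by flow cytometry. Knockout and tamoxifen treatment went together in every comparison with the control, so the design does not separate them. The KO groups had 3 and 4 days of tamoxifen, so their comparison does not separate tamoxifen dose from time after the knockout. Per the labels' protocols, total RNA was treated with DNase and mRNA was isolated for the libraries; whether the kit marked strand was not given in the sources used here.

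The authors deposited raw read counts per Ensembl gene identifier, 1 column for each of 9 libraries, with no pooling and no normalization. Per the submitters' processing notes, HISAT2 2.0.4 and the mouse genome build GRCm38 were used; the counting tool, its strand setting and the annotation release were not given in the sources used here. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and near-identical copies (defensins, the Csf2rb pair, ribosomal protein genes with pseudogenes, the Ugt1a genes that share exons, mitochondrial genes with nuclear copies) may have split or lost reads, so their single values are uncertain. The table held 57180 identifiers, of which 51884 were named through GENCODE release M21 of the same build and 5296 were kept without a symbol. Coordinates are those of that annotation, counted from 1. No row lacked a gene identifier, and 6 trailing columns of the table were empty.

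Samples were grouped by their titles into control, KO day 3 and KO day 4, with 3 libraries each. The labels do not say whether the replicates of a group were separate animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 13.1 to 93.5), and each was counted as 1 replicate. Totals ranged from 8400458 to 21484679 counts. All 9 libraries held reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, and Xist did not pass the expression filter, so a sex covariate was not fitted.

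The tests, the samples in each fit, the alternatives, the rule for named genes and 35 gene lists were fixed before the data were examined. Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (filterByExpr at its defaults of 10 counts in a library and 15 in all, TMM factors, all 9 libraries in 1 fit so that the groups share an estimate of the spread), with Benjamini-Hochberg adjustment over 13405 tested genes and a threshold of 0.05. Contrasts were KO day 3 against control, KO day 4 against control, KO day 4 against KO day 3, and the mean of both KO times against control. Fold changes are log2 values with their standard error (SE), and levels are CPM of TMM-scaled library size or, for summed markers of cell types, CPM of the counts of nuclear genes, as mean ± SD of 3 libraries. TMM factors were 1.44 to 1.83 in controls, 1.22 to 1.40 at KO day 3 and 0.40 to 0.50 at KO day 4. Gene lists with at least 3 tested genes were tested with camera from limma 3.58.1, two-sided, at a preset correlation between genes of 0.01; camera with an estimated correlation, and fry, were alternatives. Of the 35 lists 33 could be tested. A further 7 lists were written after the data had been seen, and are named as such. Intervals for ratios of low counts are exact binomial ones at 95% confidence; a gene with no count in the 3 controls was set against a floor of 3 counts over the group. Intervals and floors cover counting error only.

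Named genes are Kansl1, the other members of the NSL and MSL complexes, Lgr5, Olfm4, Ascl2 and Mki67. To these come, for each KO time against control, the 8 higher and 8 lower genes with the largest fold change. For KO day 4 against KO day 3 there are 5 each way. Such a gene needed an adjusted p under 0.05, a mean CPM of at least 5 over all libraries, every library of one group on the same side of every library of the other, and a symbol that is not a Gm number, Rik, BC, AI or AC clone, or -ps pseudogene name. For each list described, up to 4 members with the smallest adjusted p are named, or, where no member passed, the 2 with the highest mean CPM as values. Some genes that meet this rule are not reported here.

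Alternatives were RLE size factors, scaling by library size alone, no filter on low counts, a minimum mean CPM of 5, DESeq2 1.42.0, limma voom with sample quality weights, a test against a fold of 1.5, the replicate number as a block, a fit of only the groups compared, and each library left out in turn. A further 3 alternatives were added after seeing the data, namely leaving out the mitochondrially encoded genes and their nuclear copies, leaving out the 2 libraries that stood apart, and thinning the nuclear counts of every library to 2591111. The procedure was tested on simulated counts with the real library sizes, in which 200 genes were changed by a known fold before filtering. At KO day 3 it recovered 4.71% of 2-fold and 65.3% of 4-fold changes, and at KO day 4 6.09% and 61.0%. Between the KO times it recovered 2.06% and 62.4%, and for both KO times against control 14.1% and 76.8%. With 200 changed genes the adjustment is stricter than where more genes change. In the data 3021 genes were called at KO day 4, 2133 of them at 2-fold or more, so its simulated shares may be too low. The same holds for the contrasts with 1682 and 1715 genes called.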

Results

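RNA-seq counts were examined for 9 libraries of sorted Lgr5-GFP+ ISCs, 3 from control mice given corn oil, 3 from Kansl1-floxed mice after 3 days of tamoxifen (KO day 3) and 3 after 4 days (KO day 4). The libraries held from 12164479 to 17913787 in controls, 8400458 to 21484679 at KO day 3 and 11174583 to 16943055 at KO day 4. The comparisons ask how the transcriptome of ISCs differs after loss of KANSL1, and whether it differs between the 2 times.

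Kansl1 itself (ENSMUSG00000018412, chromosome 11, 104333229 to 104468861, minus strand, GRCm38) was at 8.56 ± 3.62 CPM in controls, 2.79 ± 0.22 at KO day 3 and 5.66 ± 3.05 at KO day 4 (SD, n = 3). All 3 KO day 3 libraries, at 2.81, 2.99 and 2.55 CPM, lay below the controls, at 4.46, 11.4 and 9.83. The log2 fold change at day 3 was -1.62 (SE 0.45, edgeR adjusted p = 0.12). At day 4 it was -0.63 (SE 0.46, edgeR adjusted p = 0.34), and the libraries labelled KO day 4 replicate 2 and replicate 3, at 5.09 and 8.96 CPM, lay within the range of the controls. Counts over the whole gene can keep reads from outside the deleted exons, so this level checks the labels only in part. Of the other NSL and MSL members, Hcfc1 was higher at day 4 (log2 fold change 0.74, SE 0.23, edgeR adjusted p = 0.040). Kansl2, Kansl3, Kat8, Wdr5, Phf20, Mcrs1, Ogt, Msl1, Msl2 and Msl3 did not pass the test at either time, with values from -0.66 (Msl2, day 4) to 0.59 (Ogt, day 4).

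**Figure D1:**
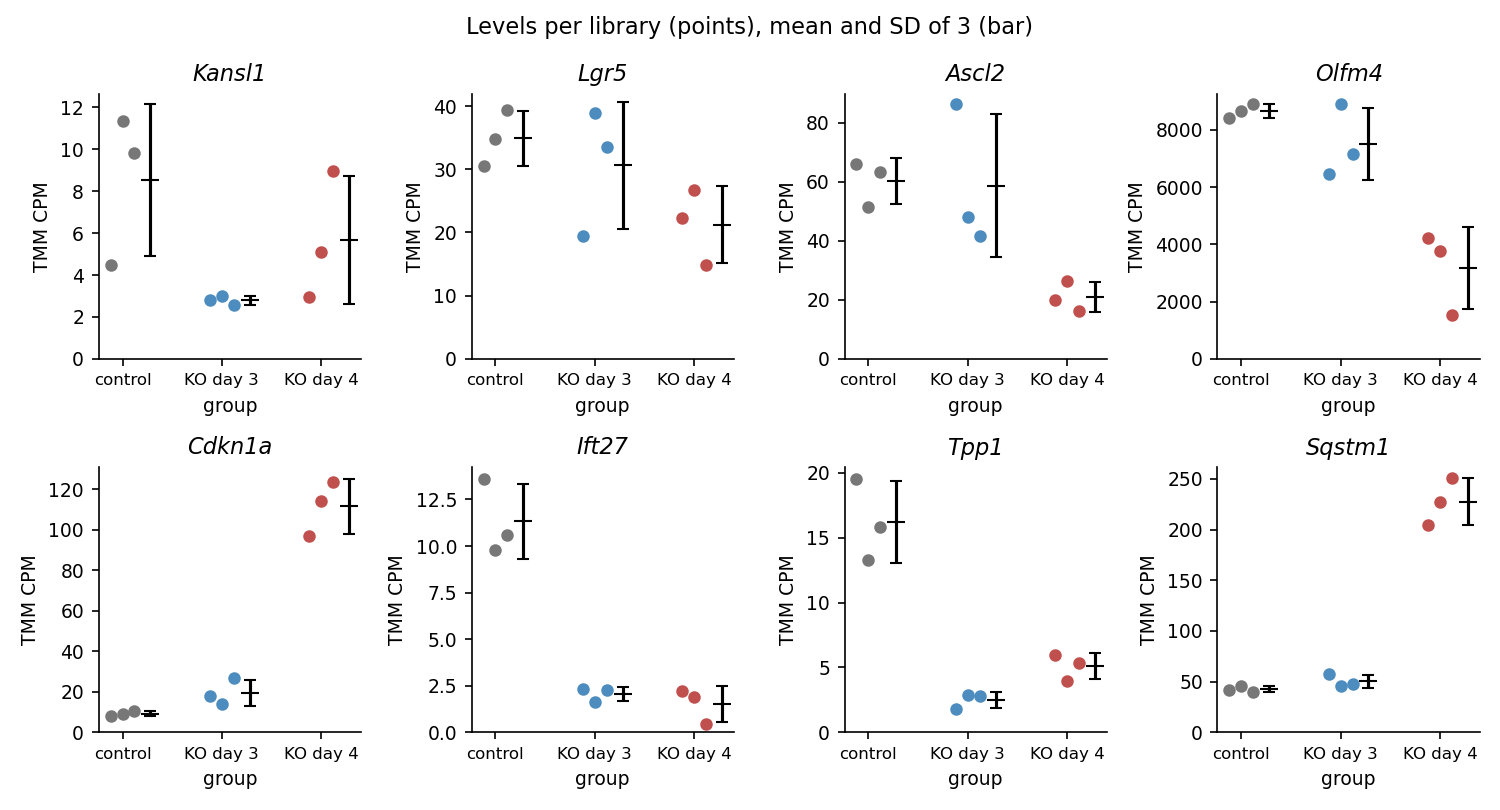
TMM-scaled CPM (vertical axes, each from 0) of 8 genes in the control, KO day 3 and KO day 4 libraries (horizontal axis); points are libraries and the black mark is the mean with its SD (n = 3). Kansl1 was lowest at KO day 3 and spread from 2.93 to 8.96 at KO day 4, while Ift27 and Tpp1 were below every control at both KO times and Cdkn1a and Sqstm1 rose at KO day 4.

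The libraries of the groups differed in composition. Transcripts of the mitochondrial genome made up 20.03% ± 5.08 of counts in controls, 27.3% ± 7.32 at KO day 3 and 69.4% ± 2.63 at KO day 4 (SD, n = 3), with the lowest KO day 4 library at 66.9% and the highest control at 25.8%. Counts of nuclear genes were correspondingly 2591111 to 4818584 per library at KO day 4 against 9824799 to 13744493 in controls. Counts of the fixed list of immune cell markers were 3.77 to 9.79 CPM of nuclear counts in controls and 88.4 to 222 at KO day 4. Defensins and Lyz1, products of Paneth cells, took 3.41% ± 1.95 of nuclear counts in controls, 4.65% ± 1.04 at KO day 3 and 15.8% ± 3.39 at KO day 4. A pair of libraries stood apart from their own groups. KO day 3 replicate 1 correlated with the others of its group at 0.914 and 0.910 across genes (log2 CPM), and the library labelled KO day 4 replicate 3 at 0.857 and 0.863, against 0.969 to 0.973 among controls.

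**Figure D2:**
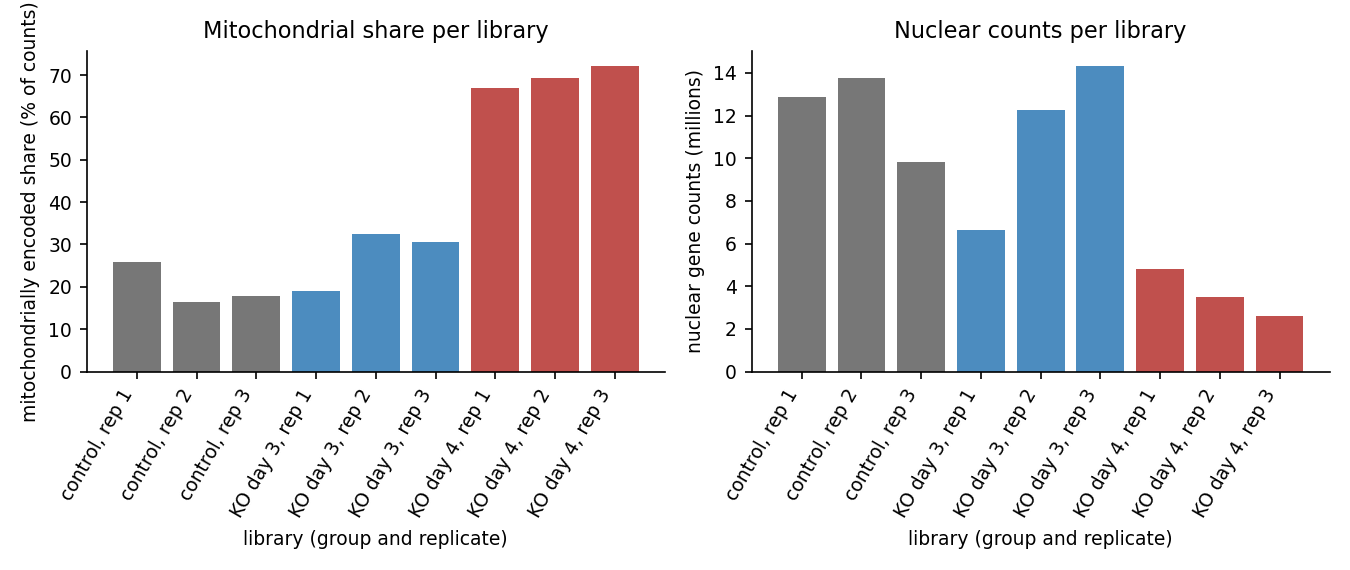
Left, percent of counts from mitochondrially encoded genes; right, counts of nuclear genes, for each of 9 libraries (horizontal axis, group and replicate). The 3 KO day 4 libraries hold 66.9% to 72.1% mitochondrial counts and the fewest nuclear counts of the 9.

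At KO day 3 Shkbp1 (ENSMUSG00000089832, chromosome 7, 27342133 to 27356019) fell furthest, at -2.95 on the log2 scale (SE 0.29, edgeR adjusted p = 0.0056), followed by Gstm2, a glutathione transferase, at -2.83. Tpp1, a lysosomal peptidase (ENSMUSG00000030894, chromosome 7, 105744811 to 105752235), fell from 16.2 ± 3.15 to 2.49 ± 0.61 CPM (SD, n = 3; log2 fold change -2.68, SE 0.31, edgeR adjusted p = 0.011). Sumf1, which activates sulfatases, had a log2 fold change of -2.43, and Tmem9, a membrane protein of endosomes and lysosomes, one of -2.76. Vps35l and Commd4, both of the endosomal Commander complex, fell by 2.44 and 2.18. In all, 59 of 13405 genes changed at adjusted p under 0.05 by edgeR's quasi-likelihood test, 19 higher and 40 lower.

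Of the 8 largest rises at day 3, 6 were genes known from mast cells: Fcer1a, Tpsb2, Cma1, Cpa3, Il1rl1 and Csf2rb2. Fcer1a had 0 counts in the controls and was at least 85.7-fold higher at day 3 (207 counts against a floor of 3 over the 3 controls). Tpsb2 had 2 control counts and 618 at day 3, a ratio of 384 (95% counting interval 106 to 3177). Their levels followed the library that stood apart, with Tpsb2 at 28.4 CPM in KO day 3 replicate 1 and 3.29 and 7.41 in the others. The remaining rises were Iigp1 (log2 fold change 5.58, SE 0.76, edgeR adjusted p = 0.019) and Igtp (2.98, SE 0.44, edgeR adjusted p = 0.020), both interferon-inducible GTPases.

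Among the fixed lists, genes of intraciliary transport, which moves cargo along the cilium, were lower at day 3, with a median log2 fold change of -1.17 over 29 tested genes (camera adjusted p = 5.28e-10). The call held with an estimated correlation (adjusted p = 0.00998). Ift27 (ENSMUSG00000016637, chromosome 15, 78159463 to 78174107) was the 1 member called alone (log2 fold change -2.45, SE 0.43, edgeR adjusted p = 0.039). Adjusted over the list alone, 4 members were called lower. Most of the list was weakly expressed: with a minimum mean CPM of 5, 7 of its genes were tested, with a median of -1.10. Immediate early genes had a median of -0.71 (camera adjusted p = 0.0083; adjusted p = 0.44 with an estimated correlation), with Fos falling by 1.60. The autophagy and lysosome list had a median of -0.16 (camera adjusted p = 0.028; adjusted p = 0.34 with an estimated correlation), with no member called.

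A further 16 fixed lists had higher values at day 3 by camera at the preset correlation, and none of these calls held with an estimated correlation, where the lowest adjusted p was 0.32. The largest medians were those of the immune cell markers (3.13 over 8 genes, or 2.94 with low-count genes at their count ratio or floor), MHC class II (2.02), tuft cell markers (1.10), cholesterol synthesis (0.78), mitochondrially encoded transcripts (0.77) and enteroendocrine markers (0.67). Immune marker counts were highest in KO day 3 replicate 1, which stood apart, at 51.8 CPM of nuclear counts against 9.87 and 14.6 in the others and up to 9.79 in controls. The tuft cell gene Rgs13 was at 3.84 CPM there against 1.08 and 1.74. Of MHC class II, 7 of 7 members were higher adjusted over the list alone and none over all genes; Cd74 was at 165 CPM in controls and 608 at day 3, and H2-Ab1 at 76.5 and 310. Of cholesterol synthesis, 7 of 22 were higher adjusted over the list alone, and Cyp51 was at 43.1 CPM in controls and 115 at day 3. For the unfolded protein response (median 0.56) 11 of 19 were, and Manf, a secreted protein of the endoplasmic reticulum stress response, rose over all genes (0.82, SE 0.15, edgeR adjusted p = 0.049). The other lists were NRF2 targets (0.49), Paneth markers (0.48), cytosolic ribosomal proteins (0.43), cell cycle (0.38), p53 targets (0.37), ribosome biogenesis (0.36), the integrated stress response (0.36), the interferon response (0.36) and nuclear-encoded oxidative phosphorylation (0.29). In p53 targets, 5 members were higher adjusted over the list alone, while Dcxr, a carbonyl reductase, fell (-1.48, SE 0.23, edgeR adjusted p = 0.026). Stem cell markers did not pass the test at day 3 (median -0.10 over 28 genes, camera adjusted p = 0.68), with Lgr5 at -0.18, Olfm4 at -0.21, Ascl2 at -0.04 and the proliferation marker Mki67 at 0.47, none of which passed the test.

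The day 3 count was not stable. It was 0 without control replicate 2 and 0 without KO day 3 replicate 3 (edgeR, with 1333 and 1747 genes at unadjusted p under 0.05), 5 and 3 without control replicates 1 and 3, 35 and 38 without replicate 2 of KO day 3 or KO day 4, 345 without KO day 4 replicate 3 and 646 without the 2 libraries that stood apart. DESeq2 called 818, limma voom 1423 and edgeR with library-size scaling 39 higher and 479 lower.

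At KO day 4, 3021 genes changed, 1484 higher and 1537 lower. Pipox, a peroxisomal oxidase, fell furthest (log2 fold change -5.53, SE 0.68, edgeR adjusted p = 0.00058), with Ces1d, a carboxylesterase, at -5.52. Dmbt1, a secreted mucosal glycoprotein (ENSMUSG00000047517, chromosome 7, 131032053 to 131121630), was at 649 CPM in controls and 30.99 at day 4 (log2 fold change -4.39, SE 0.36, edgeR adjusted p = 0.00010). Ccn1, a matricellular protein, was at -4.30, the histone deacetylase Hdac11 at -4.15, Gstm2 at -3.92, the oxysterol hydroxylase Cyp39a1 at -3.71 and Vwa2 at -3.49. The 8 largest rises, Fcer1a, Csf2rb, Tpsb2, Cma1, Ms4a2, Il1rl1, Cpa3 and Csf2rb2, were again genes known from mast cells. Against the floor, Fcer1a was at least 1399-fold, Csf2rb at least 601-fold and Ms4a2 at least 465-fold higher. For genes with 1 to 3 control counts, the ratio was 4329 for Tpsb2 (95% counting interval 1197 to 35768), 3355 for Cma1 (1147 to 16282), 3617 for Il1rl1 (647 to 143003) and 2117 for Csf2rb2 (585 to 17502).

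With library size alone in place of TMM, the median log2 fold change of all genes was -0.39 at day 3, -1.95 at day 4 and -1.54 between the KO times, against -0.0169, -0.0626 and -0.0248 with TMM. Changes given here are those with TMM. With library size alone, 288 genes were called higher and 10769 lower at day 4.

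Camera at the preset correlation called 18 lists at day 4, and none was called with an estimated correlation. By fry 21 lists were called, of which 16 were among the 18. Transcripts that mark ISCs fell at day 4. Of 28 tested markers 14 fell and 1 rose, with a median of -0.81 (camera adjusted p = 0.00033; adjusted p = 0.34 with an estimated correlation), and 16 fell adjusted over the list alone. Ascl2, a stem cell transcription factor (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264), fell from 60.2 ± 7.87 to 20.9 ± 4.996 CPM (SD, n = 3; log2 fold change -1.52, SE 0.28, edgeR adjusted p = 0.0039). Smoc2 had a log2 fold change of -1.21, Cdca7 of -1.18, Slc12a2 of -1.21 and Olfm4 of -1.45 (SE 0.33, edgeR adjusted p = 0.010). Lgr5, whose promoter drives the sorted GFP, was at 34.9 ± 4.395 CPM in controls and 21.3 ± 6.03 at day 4 (-0.71, SE 0.28, edgeR adjusted p = 0.092), and Mki67 was at 0.37 (edgeR adjusted p = 0.23). In the same libraries 69.4% of counts were mitochondrial. Wnt targets went both ways, with Wnt3 (2.01) and Nkd1 (2.14) higher, Ascl2 and Tnfrsf19 (-1.45) lower, and no call for the list (camera adjusted p = 0.93). In the Notch and secretory fate list, the receptor Notch1 fell by 1.41 while the secretory factors Spdef (1.76), Gfi1 (2.38) and Atoh1 (1.21) rose, and the list was not called (camera adjusted p = 0.92).

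Markers of secretory lineages were higher at day 4, in the libraries whose defensin and Lyz1 share was 15.8% and whose nuclear counts were lowest. Of Paneth cell markers 14 of 14 rose (median 2.48, camera adjusted p = 2.71e-17; adjusted p = 0.13 with an estimated correlation), among them Lyz1 (2.79), the lectin Itln1 (2.68), Clps (2.56) and Habp2 (2.94, SE 0.37, edgeR adjusted p = 0.00066). Of enteroendocrine markers 14 of 20 rose (median 2.67, camera adjusted p = 5.91e-10; adjusted p = 0.071 with an estimated correlation), with the serotonin-synthesis enzyme Tph1 at 4.84 and the hormone genes Tac1 at 3.54, Sst at 2.72 and Gip at 2.59. Of tuft cell markers 10 of 15 rose (median 4.82, camera adjusted p = 4.3e-16; adjusted p = 0.053 with an estimated correlation), with Avil at 5.88, Rgs13 at 6.77 and Alox5 at 8.17. Alox5 is also expressed by blood cells. Avil, Rgs13, Alox5 and Tph1 ordered the KO day 3 libraries as the mast cell gene Tpsb2 did, highest in replicate 1 and lowest in replicate 2. Tac1, Sst and Gip ordered them otherwise. Whether these rises come from the named lineages or from mast cells or their RNA was not tested. Of goblet cell markers 6 of 13 rose and 1 fell (median 1.05, camera adjusted p = 0.00048; adjusted p = 0.34 with an estimated correlation), with Spink4 at 2.28, the mucin Muc2 at 1.89, Sytl2 at 3.48 and Tff3 at 1.10. Enterocyte markers were not called as a list (median -0.42, camera adjusted p = 0.13): Mep1a (-3.07), Slc5a1 (-0.92) and Dgat1 (-1.57) fell and Krt20 (2.35) rose. Immune cell markers rose in 7 of 8 tested genes (fitted median 6.17, or 6.26 with low-count genes at their count ratio or floor; camera adjusted p = 3.56e-06; adjusted p = 0.19 with an estimated correlation). Gzmb rose from 0.065 to 33.3 CPM. Ptprc was at least 143-fold and Tyrobp at least 86.6-fold higher, and Fcer1g had a ratio of 94.7 (95% counting interval 31.1 to 470). The immune list summed to 426, 420 and 575 counts in KO day 4 replicates 1, 2 and 3. Of these, Gzmb gave 134, 222 and 219 and Lyz2 gave 124, 66 and 178. Whether cells other than mast cells gave these counts was not tested. Stromal and red blood cell lists had too few genes past the filter to be tested; stromal marker counts were 3.05 to 8.24 CPM of nuclear counts in controls and 46.9 to 91.1 at day 4, and red blood cell marker counts 0.146 to 2.14 and 0.

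**Figure D3:**
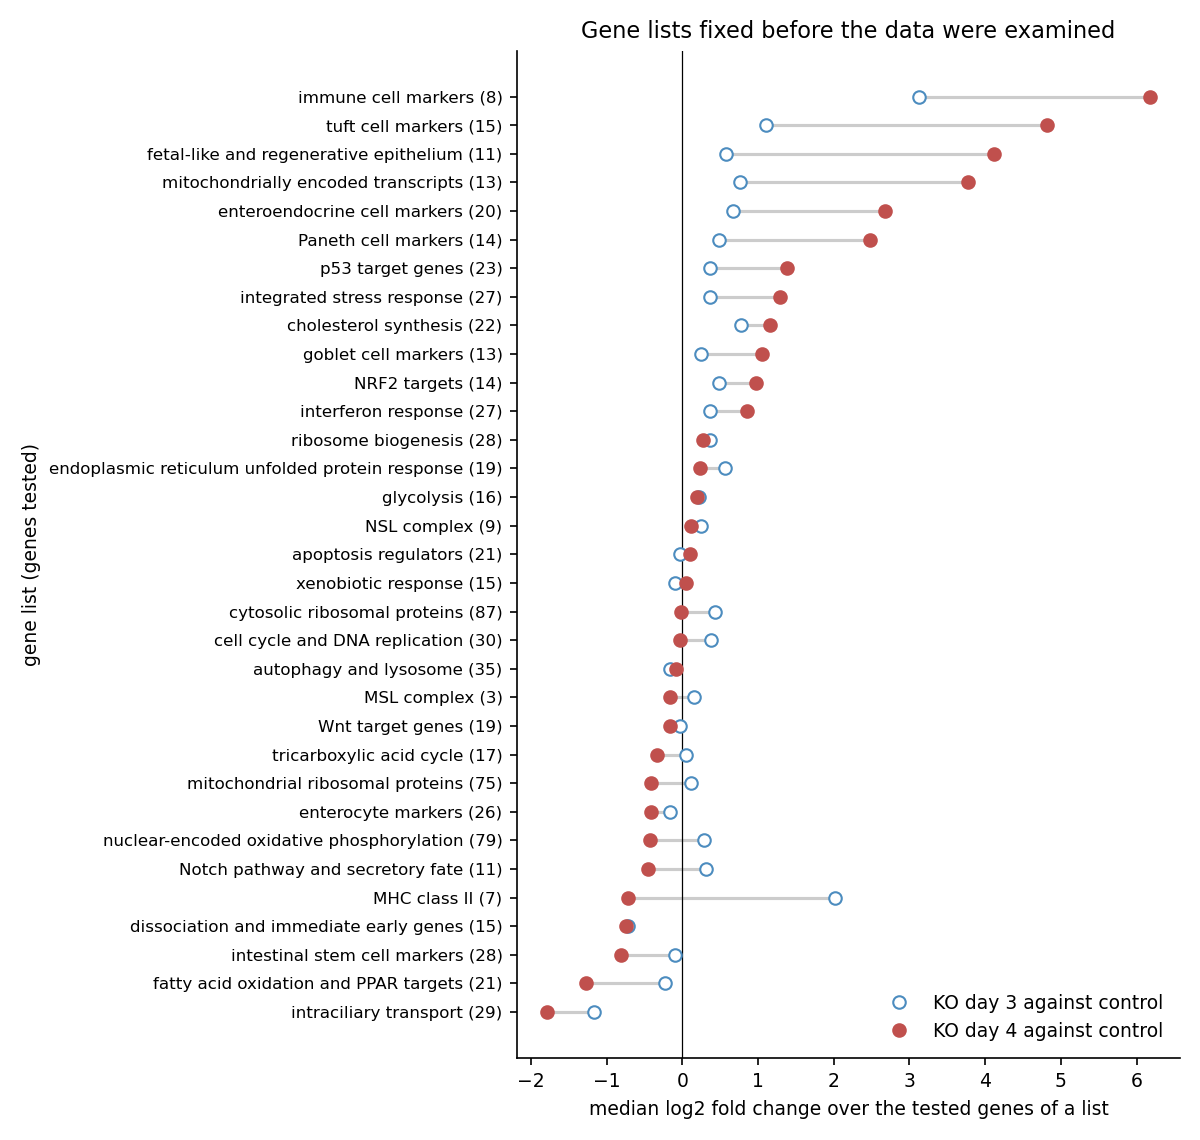
Median log2 fold change (horizontal axis) over the tested genes of each of 33 gene lists fixed before the data were examined (vertical axis, genes tested in brackets) for KO day 3 (open circles) and KO day 4 (filled circles) against control. Intraciliary transport has the lowest median at both times (-1.17 and -1.78), and MHC class II has medians of 2.02 and -0.72.

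Of p53 targets 14 of 23 rose (median 1.38, camera adjusted p = 5.05e-14; adjusted p = 0.053 with an estimated correlation; -0.54 with library-size scaling). The cell cycle inhibitor Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose from 9.21 ± 1.14 to 112 ± 13.5 CPM (SD, n = 3; log2 fold change 3.60, SE 0.25, edgeR adjusted p = 3.3e-05), Plk2 by 2.93, Ccng1 by 2.11 and Phlda3 by 3.56. Of the integrated stress response, the program downstream of eIF2 phosphorylation, 16 of 27 rose (median 1.29, camera adjusted p = 2.87e-10; adjusted p = 0.091 with an estimated correlation), with Sesn2 at 2.10, Mthfd2 at 1.89, Chac1 at 5.02 and the transcription factor Atf4 at 1.29. Of NRF2 targets, the antioxidant genes, 10 of 14 rose (median 0.97, camera adjusted p = 1.85e-08; adjusted p = 0.13 with an estimated correlation), among them Srxn1 (1.99), Hmox1 (5.70), Osgin1 (4.397) and Me1 (3.30). The autophagy receptor Sqstm1 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827) rose by 2.41 (SE 0.16, edgeR adjusted p = 2.5e-05). Its list, autophagy and lysosome, had 3 members higher and 5 lower (median -0.09, camera adjusted p = 0.94), including falls of Pik3r4 (-3.11) and Pik3c3 (-2.29), which initiate autophagosomes, and Vamp8 (-1.16). Fetal-like and regenerative genes rose in 8 of 11 (median 4.11, camera adjusted p = 1.05e-08; adjusted p = 0.071 with an estimated correlation), with Anxa2 at 1.97, Il1rn at 6.69, Ly6a at 5.77 and Anxa3 at 4.11, while Ccn1 fell. Interferon response genes rose in 7 of 27 (median 0.86, camera adjusted p = 0.0023; adjusted p = 0.50 with an estimated correlation), with Irf7 at 2.49, Usp18 at 3.72, Cxcl10 at 5.62 and Gbp2 at 3.48. Immediate early genes went both ways, with Fos (-2.29), Dusp1 (-2.64) and Zfp36 (-1.19) lower and Jund (0.86) higher (camera adjusted p = 0.15). Among the named NRF2 and fetal-like genes, Hmox1 and Il1rn were, as Tpsb2 was, highest in KO day 3 replicate 1 and lowest in replicate 2. The others were not. Mast cell markers other than Kit summed to 678 to 1964 CPM of nuclear counts in the KO day 4 libraries, against 0.509 to 1.31 in controls. Kit, which was left out after its values were seen, gave 146 to 169 of the 151 to 179 mast cell marker counts of a control library.

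Metabolic genes split by genome and by pathway at day 4. All 13 mitochondrially encoded mRNAs rose (median 3.77, camera adjusted p = 2.25e-35; adjusted p = 0.053 with an estimated correlation), among them mt-Nd1 (4.07), mt-Nd3 (3.13), mt-Co2 (3.67) and mt-Nd6 (4.96). Of the nuclear-encoded subunits of oxidative phosphorylation 18 of 79 fell and none rose (median -0.42, camera adjusted p = 8.2e-05; adjusted p = 0.57 with an estimated correlation), with Ndufb3 at -1.40. Mitochondrial ribosomal proteins fell in 19 of 75 (median -0.42, camera adjusted p = 0.00052; adjusted p = 0.49 with an estimated correlation), with Mrps33 at -1.49 and Mrpl44 at -1.14. Fatty acid oxidation and PPAR targets fell in 12 of 21 and rose in 1 (median -1.27, camera adjusted p = 1.68e-05; adjusted p = 0.34 with an estimated correlation), including Eci1 (-1.08), Acadm (-1.004), Acadvl (-1.60) and Hadha (-1.08). Cholesterol synthesis rose in 12 of 22 (median 1.16, camera adjusted p = 4.06e-08; adjusted p = 0.31 with an estimated correlation), with Fdft1 at 1.72 and Hmgcs1 at 2.09. The tricarboxylic acid cycle (5 of 17 fell, with Fh1 at -0.68; camera adjusted p = 0.081), glycolysis (4 of 16 rose and 2 fell, with Hk1 at 2.49 and Pdk1 at -1.35; camera adjusted p = 0.26) and the xenobiotic response (3 of 15 fell, Ugt1a6a at -3.21, Ces2a at -2.23 and Ugt1a1 at -2.17; camera adjusted p = 0.35) were not called as lists. Ribosome biogenesis was called higher (median 0.28, camera adjusted p = 0.040; adjusted p = 0.63 with an estimated correlation), and cytosolic ribosomal proteins (median -0.01), the unfolded protein response (0.24, with Edem1 at 1.28), apoptosis regulators (0.10, with Bak1 at -1.42), MHC class II (-0.72), the NSL (0.11) and MSL (-0.16) complexes and the cell cycle list (-0.03, with Mcm6 at -0.50, Gins2 at -0.97 and Foxm1 at 1.54) were not.

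Intraciliary transport genes were lower at day 4 too, with 11 of 29 lower and none higher (median -1.78, camera adjusted p = 4.99e-05; adjusted p = 0.053 with an estimated correlation). The number lower was 6, 3 and 3 without control replicates 1, 2 and 3, and 16 without the 2 libraries that stood apart. Ift27 fell by 2.81 (SE 0.46, edgeR adjusted p = 0.0021), Ift52 by 1.44, Ttc21b by 2.76 and the BBSome subunit Bbs2 by 2.17. Some of these falls rest on few counts. Ttc21b had 124, 190 and 137 counts in the controls and 11, 3 and 3 at KO day 4, and Bbs2 81, 137 and 103 against 11, 3 and 4. Over both KO times averaged, 10 of 29 fell, with a median of -1.46 (camera adjusted p = 1.13e-08; adjusted p = 0.017 with an estimated correlation). Between the KO times none passed the test (camera adjusted p = 0.48), where Ift20 was at 0.78 and Ift52 at -0.37.

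The day 4 count was 1744, 1588 and 1750 without control replicates 1, 2 and 3, and 1278 against a fold of 1.5. It was 4112 without the 2 libraries that stood apart, of which 2844 were among the 3021.

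**Figure D4:**
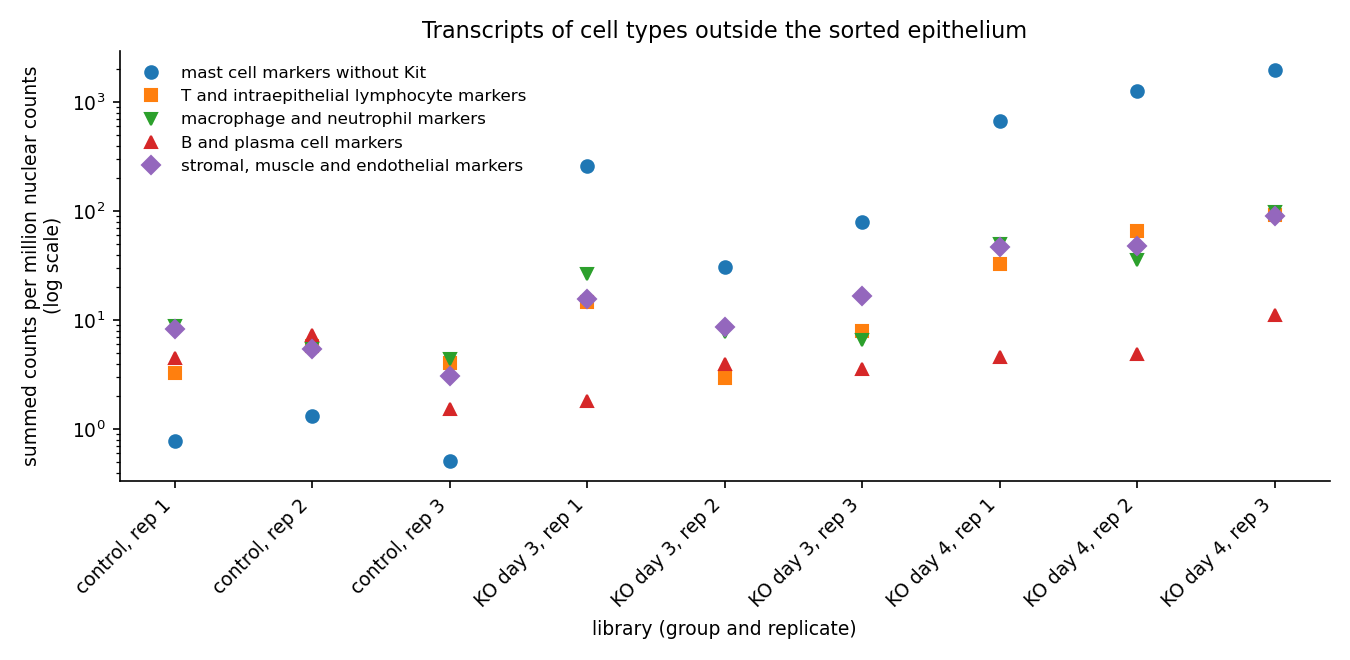
Summed CPM of nuclear counts (vertical axis, log scale) of markers of 5 other cell types in each library of the control, KO day 3 and KO day 4 groups; points are libraries. Mast cell markers without Kit were at 0.509 to 1.31 in controls, 31.1 to 257 at KO day 3 and 678 to 1964 at KO day 4; all but the stromal list were written after the data had been seen.

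The direct comparison of KO day 4 with KO day 3 called 1682 genes, 874 higher and 808 lower. Tuft cell genes led the rises, with Sh2d6 at 5.85 and Dclk1 at 5.18, together with Fam129a, a stress-induced gene (5.25, SE 0.34, edgeR adjusted p = 4.4e-05), and the mast cell gene Ms4a2 (4.63). Ces1d (-4.62), Pipox (-4.23), Dmbt1 (-4.19), Igtp (-3.59) and the glucuronosyltransferase Ugt1a6a (-3.52) were lowest. In this contrast Cdkn1a was at 2.51 and Sqstm1 at 2.18. Of the lists, 10 were higher and 8 lower by camera at the preset correlation, and none was called with an estimated correlation (6 at unadjusted p under 0.05), while fry called 17. The higher ones were Paneth (14 of 14 rose, median 2.09, Habp2 at 2.38), goblet (0.76), enteroendocrine (1.81), tuft (3.47), p53 targets (1.23), mitochondrially encoded transcripts (3.04), the integrated stress response (0.75), NRF2 targets (0.80), fetal-like genes (2.34) and immune markers (2.30). Dcxr, lower at day 3, was among the p53 targets that were higher at day 4 than at day 3 (2.04). The lower lists were stem cell markers (9 of 28 fell and 1 rose, median -0.70, Smoc2 at -0.96), nuclear-encoded oxidative phosphorylation (41 of 79 fell, -0.69, Cox6a1 at -1.15 and Cox7b at -0.95), mitochondrial ribosomal proteins (-0.46, Mrps33 at -1.37), cytosolic ribosomal proteins (17 of 87 fell, -0.43, Rpl30 at -1.08 and Rps15a at -0.96), the cell cycle (-0.36, Mcm6 at -0.87 and Mcm7 at -0.81), the tricarboxylic acid cycle (-0.40), fatty acid oxidation and PPAR targets (-0.95) and MHC class II (-2.77, H2-DMa at -3.12, H2-Aa at -3.50 and H2-Ab1 at -2.84). The chaperones Hsp90b1 (-0.88) and Pdia4 (-1.02) were lower at day 4 than at day 3, and their list, the unfolded protein response, was not called (camera adjusted p = 0.10). The mitochondrial share rose from 27.3% to 69.4% between the same groups. The count was 806 with only the 6 KO libraries in the fit, 648 without KO day 3 replicate 2, 926 and 1011 without KO day 4 replicates 2 and 3, 409 against a fold of 1.5 and 3030 with DESeq2.

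Both KO times averaged differed from control in 1715 genes, 749 higher and 966 lower. Fold changes at the 2 times went together, with a Pearson correlation of 0.64 across 13405 genes, which are not independent replicates. Unchanged groups simulated against the same 3 controls gave 0.43 (mean of 50). The covariance was 0.86 against 0.15 simulated, a difference of 0.71, and the share of genes with the same sign 68.1% against 65.6%. Of the 19 genes higher at day 3, 13 were higher at day 4, and of the 40 lower 31 were lower, with no gene called in opposite directions. Independent lists of these sizes, which leave out the shared controls, would have 2.10 and 4.59 genes in common. The simulated unchanged groups had 0 and 0. Groups without a change give few calls at all, so this value cannot show how many shared calls the controls add. The controls were too few to split, so part of the excess may come from the shared controls. The averaged count was 579, 329 and 529 without control replicates 1, 2 and 3, 1004 without KO day 3 replicate 3, 433 against a fold of 1.5, 3440 without the 2 libraries that stood apart, 2853 with DESeq2 and 4100 with limma voom.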

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

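The comparison of the lists for an equal rise of other cell types and the bound on mitochondrial DNA were chosen only after the result was seen; the other tests were written before theirs. What flagged the following results was a tested difference between the 2 KO times. KO day 4 differed from KO day 3 in 1682 genes, of which 421 had opposite directions against control and were called against control at only one time. No gene was called in opposite directions at both times, so the direction at the other time is uncertain for these genes. Among lists called by camera at the preset correlation, the cell cycle and DNA replication list had a median log2 fold change of -0.36 between the times (adjusted p = 0.43 with an estimated correlation). Nuclear-encoded oxidative phosphorylation was at -0.69, mitochondrial ribosomal proteins at -0.46 and MHC class II at -2.77 (camera adjusted p = 0.26 for each with an estimated correlation), so none of these 4 calls held there.

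The mitochondrial share of counts was 69.4% at KO day 4 against 20.03% in controls. Mitochondrial DNA was weighed by 2 tests that pointed opposite ways. The test written beforehand gave a rank correlation of -0.659 between fold change and control level per base over the 13 mRNAs, which met its bound for added DNA, although this value shares the control level with the fold change. The bound chosen afterwards allowed an equal amount per base to supply at most 0.0856% of the rise, since mt-Nd6 rose by only 0.105 CPM per base and the median mRNA by 131; it holds only for DNA covered evenly, so mitochondrial DNA stays open as a source. Loss of long cytosolic transcripts by degradation would lower long genes, and the correlation of fold change with exon length was 0.173, the other way; stressed or dying cells after loss of KANSL1 or after tamoxifen could give the same share, and the design has no group that separates them.

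Mast cell transcripts in sorted epithelial cells may come from mast cells or their RNA in the sort, as most of the mast cell genes kept similar ratios to each other across the KO libraries: the median SD was 0.354 on the log2 scale, with 11 of 15 genes at 0.149 to 0.476. Rgs1 (0.656), Ms4a2 (0.802), Kit (0.927) and Mcpt2 (1.53) did not, and are named after their values were seen. The list was written after 7 of its 18 genes had been seen, so its medians (6.88 and 9.31 at the 2 times, or 5.99 and 9.38 with low-count genes at their count ratio or floor) are given without a test. A plain dilution of stem cells by all other cells would raise the lists alike, and the medians of 6 lists spread over 9.73, or from -0.42 (enterocyte) to 4.82 (tuft) over the 5 fixed ones without mast cells. Macrophage and neutrophil markers (3 of 6 rose at day 4, median 3.64) and T cell markers (32.8 to 92.6 CPM of nuclear counts against 3.26 to 5.75) also had higher values. Gzmb alone had 134, 222 and 219 counts in the KO day 4 libraries, where the T cell list summed to 158, 231 and 240. A rise of other T cell genes was not shown. B cell and plasma cell markers were at 4.57 to 11.2 CPM of nuclear counts against 1.53 to 7.35.

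Intraciliary transport and lysosomal enzyme genes had medians below 0 at both times, and length, GC content and expression are unlikely to explain this at day 3: of matched lists, 0% of 10000 reached the day 3 median of either list (matched medians -0.30 and -0.07). The call of intraciliary transport did not hold at day 4 with an estimated correlation (camera adjusted p = 0.053), and its day 3 median was -1.14 without the low-depth KO day 3 replicate 1 and -1.33 to -1.05 over all leave-one-out fits. The lysosomal list was written after 7 of its genes had been seen; over the other 41 the day 3 median was -0.59. Loss of KANSL1 could lower both groups directly, but tamoxifen was given to the same mice, and Kansl1 lay within the control range in KO day 4 replicates 2 and 3.

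Regrouping the libraries tests whether other splits give as many changed genes. For KO day 3, KO day 4 and the KO times against each other, the real split was 1 of 10 and gave 337, 3228 and 806 genes in a fit of the 2 groups, where the highest other split gave 1 each time; 10 splits are too few for a test. For all KO libraries against control, 2 of 84 splits gave as many genes as the real one, itself included. The real split gave 62 and the highest other 2607, which sets the 3 KO day 4 libraries against the remaining 6. In such fits the KO day 4 libraries thus differed from the rest in more genes than all KO libraries did from control. What drives the averaged contrast was not tested.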

How the results depend on the processing

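Leaving out mitochondrial genes, the 2 libraries that stood apart, or depth beyond 2591111 nuclear counts was chosen only after the result was seen. The day 3 count of 59 genes was the least stable: 518 with library size (39 higher, 479 lower), 317 without a filter, 16 against a fold of 1.5, 9 with the replicate block, 337 with only 2 groups in the fit, 818 with DESeq2, 1423 with voom, 646 without the 2 libraries apart, 20 thinned to one depth, and 0 to 345 leaving out each replicate. The day 4 count of 3021 became 11057 with library size (288 higher), 1278 against a fold of 1.5 and 1588 to 3839 leaving out each replicate. Between the KO times 1682 became 9508 (189 higher), 409, 806 with 2 groups in the fit, 3030 with DESeq2 and 648 to 1802. The averaged count of 1715 became 9914 (220 higher), 433, 2853 with DESeq2, 4100 with voom, 3440 without the 2 libraries and 329 to 2158. The cause of these shifts was not tested. Counts stayed within 1.5 times with RLE factors. With an estimated correlation 1, 0 and 0 lists were called at day 3, at day 4 and between them. By fry 3, 21 and 17 were called, of which 3, 16 and 14 were among the main calls. Leaving out each replicate gave 17 to 24, 18 to 21 and 18 to 20. The correlation of fold changes was 0.535 to 0.670. Kansl1, averaged over both times, was at -2.33 with library size, -1.19 without a filter, -1.10 with DESeq2, -1.30 with voom and -1.37 without the 2 libraries, where it passed the threshold, and at -1.43 to -0.86 leaving out each replicate, where it passed only without KO day 4 replicate 3 (-1.37). Directions turned only with library size: at day 4 Kansl2 -1.35, Kansl3 -1.56, Kat8 -1.89, Wdr5 -1.80, Hcfc1 -1.13, Ogt -1.28, Mki67 -1.4998, Spdef -0.15, Atoh1 -0.67, Muc2 -0.0226, Tff3 -0.79, Foxm1 -0.39, Fdft1 -0.17, Mthfd2 -0.0421, Atf4 -0.59, Edem1 -0.63 and Jund -1.04, and between the times Ift20 -0.80. Of named genes called at day 4, 80 of 119 kept their call in every setting that tested them; at day 3 all 24 lost it in some leave-one-out fit. Deviations of libraries with the same replicate number correlated at -0.05 to 0.13, and those with unlike numbers at -0.09 to 0.09. Between control and KO day 3 the like pairs, at 0.07, 0.03 and 0.13, lay above every unlike pair (at most 0.01). This did not hold in the other comparisons, so whether the numbers pair the samples stays open. The block called 2680, 1537 and 1308 genes in the contrasts other than day 3. Sex as a covariate was not run, since every library held Y-linked counts. Low nuclear depth at KO day 4 limits calls of weakly expressed genes.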

Other observations

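The lists of lysosomal enzymes and of interferon gamma and antigen presentation genes were chosen only after the result was seen, and the divergent promoter tests were written before theirs. Enzymes of the lysosome were lower in the KO libraries beyond Tpp1. At day 3, 7 of 48 fell (median -0.79), among them Fuca2 (-1.83) and Man2b2 (-2.74), but 0 without any 1 control replicate or without KO day 3 replicate 3 (medians -0.86 to -0.69), and 15 without KO day 4 replicate 3. At day 4, 25 of 48 fell (median -1.02), with the mannosidases Man2b1 (-1.63) and Manba (-2.50), the saposin precursor Psap (-0.99), Aga (-2.09) and Ppt1 (-1.60). Of the 41 not seen beforehand, 1 fell at day 3 and 14 adjusted over the list alone, and 18 fell at day 4 (camera adjusted p = 0.00391 and 0.0342 with an estimated correlation).

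Some genes induced by interferon gamma rose at day 3 and were lower at day 4 than at day 3. The list was written after Iigp1, Igtp and other members had been seen at day 3, so it is given without a test; the fixed interferon list had no member called at day 3. At day 3, 5 of 29 rose over all genes (median 1.59), with Irgm2 at 2.49 and the peptide transporter Tap1 at 2.19. Against control at day 4, 4 rose and 6 fell, including H2-T3 (-1.71), the immunoproteasome subunit Psmb10 (-1.26) and Ifi47 (-1.59). Between the times 16 fell (median -1.13), with Psmb10 at -1.66 and Ifi47 at -2.96.

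The NSL complex acts at promoters of housekeeping genes, many of which are divergent, so genes that fell could lie more often at promoters shared with a neighbour. They did not do so more often than matched genes: 3 of 40 at day 3 (7.5% against 15.7% of matched genes, permutation p = 0.965) and 218 of 1468 at day 4 (14.9% against 15.2%, p = 0.678). Only protein-coding genes outside the mitochondrial genome were tested, which are 1468 of the 1537 genes lower at day 4. Of such genes that rose, 1 of 17 at day 3 (5.88% against 15.4%, permutation p = 0.943) and 137 of 1367 at day 4 (10.02% against 14.7%, p = 1) lay there, by the same one-sided permutation test for more. A p near 1 in this test means that nearly all permutations had a share as high or higher. The share of the genes that rose at day 4 was thus below that of matched genes, and a test for fewer was not run.

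The rank correlation of exon length with the deviation from the control mean was -0.186 in control replicate 1, -0.165 in KO day 3 replicate 1 and 0.0633 to 0.171 in the other libraries, so these 2 libraries differ from the rest of their groups in this value.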
